A study of Homo sapiens with 5 samples.

How the data were processed

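Total RNA of HaCaT cells was profiled by RNA sequencing in 5 libraries, 2 labelled as controls and 3 labelled as AHNAK knockdown. HaCaT is an established human keratinocyte line that proliferates without limit and keeps the ability to differentiate. The groups and the replicate numbers were taken from the labels. The sample labels call the treated cells a knockdown, while the series' design text calls them a knockout. The labels do not state whether replicates came from separate cultures, nor whether the 3 knockdown samples received different interfering RNAs, so p-values measure only the spread between these samples, which may be technical.

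The authors deposited 1 table of FPKM values (fragments per kilobase of transcript, scaled to the mapped fragments of each library), with 1 row per gene symbol and 1 column per library. Per the submitters' processing notes, HISAT2 version 2.0.1 and StringTie version 2.0.6 were used, and the genome builds GRCh38 and mm9 are named there without a role. The annotation and whether counting used strand are not given in the sources used here. The table held 27933 symbols, of which 26.93% were at 0 in every library. It held 0 mitochondrially encoded genes, and 25 symbols had been turned into dates and were not matched to genes. FPKM sums ranged from 374214.8 in control replicate 1 to 420540.9 in knockdown replicate 3.

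FPKM values carry no read totals, and the absolute depth is unknown. Values of low genes (under 0.3 FPKM in both libraries of a pair) were compared between libraries, with ratios rounded to 5 decimals. Within a set, the most frequent ratio was taken as the worth of 1 read in one library relative to another, and it held for 22.2%, 20.1% and 25.1% of low genes in the pairs formed by control replicate 1 and knockdown replicates 1 and 3. It held for 17.0% in the pair of control replicate 2 and knockdown replicate 2, and for at most 3.96% in every other pair; in 3 of these 6 pairs (control replicate 2 with knockdown replicates 1 and 3, and knockdown replicates 2 and 3) the most frequent ratio was 0.16281, 0.18675 and 0.17368, far from the ratio of the read worths used, so the scale between the sets is not settled. The first 3 libraries are called set A here and the other 2 set B. Within set A, relative read totals were 100.0% for control replicate 1 and 81.7% and 71.2% for knockdown replicates 1 and 3. The values were FPKM and not read counts, so no count test was run. No label describes the sets. Each set holds libraries of both groups, so differences were also computed within set A (1 control, 2 knockdown) and set B (1 control, 1 knockdown).

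Expression was analysed as log2(FPKM + 0.5) for the 12196 genes with a mean of at least 1 FPKM over the 5 libraries, with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), knockdown against control with no covariate. P-values were two-sided and adjusted with the Benjamini-Hochberg method, with a threshold of 0.05. A log2 difference on this scale understates the change of low genes. Of 34 gene lists, 29 had at least 5 tested members and were tested with camera (limma) at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the lists; camera with an estimated correlation and the self-contained test fry were alternatives. A group of 2 against 3 libraries has 10 possible splits, so an exact permutation test could not go below 0.1.

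The groups, the tests, the lists and the first set of alternatives were fixed before the data were examined, as was the rule for the genes named. That rule took AHNAK, then the 12 genes with the largest rise and the 12 with the largest fall among genes past the threshold with a mean of at least 5 FPKM and no overlap between groups. Where no gene passed, it took the 5 of smallest unadjusted p in each direction, named as not passing. It further took the 4 members of smallest p of each of the 9 main lists, the 3 of smallest p of each other list past the threshold, and a fixed set reported whatever its result: AHNAK2, OSMR, IL6ST, IL31RA, STAT3, SOCS3, KRT1, KRT10, IVL, KRT5, KRT14, MKI67, PCNA, S100A10 and ANXA2. Of the genes this rule took, 4 are not reported here by name. The alternatives were other pseudocounts, filters, scalings, variance models, library weights, a replicate block, each library left out in turn, other list tests and other thresholds. A term for the set of libraries, a loess correction (span 0.3) of each library for GC content and transcript length, and camera with a variance trend were added after the data had been seen.

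Gene identifiers, coordinates, lengths and GC content were taken from GENCODE release 29 (GRCh38) by symbol, which 96.5% of the tested genes matched. The limma step was tested on simulated data for this comparison, with 12196 simulated genes in each of 10 runs. It called 48.0% of changes of 1 on the log2 scale, 84.6% of changes of 1.5, 95.6% of changes of 2 and 0.4% of changes of 0.5. Of 1208 calls over all runs, 65 were of unchanged genes. The simulated values held independent normal noise for each gene and library, with no shifts shared between genes and no sets of libraries. These rates may therefore not hold for the real data. Python 3.11.15 with pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the read steps and the figures.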

Results

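RNA of HaCaT keratinocytes was compared between 2 control libraries and 3 libraries labelled as AHNAK knockdown. AHNAK encodes a very large scaffold protein of the plasma membrane and cytoplasm. The study asked what AHNAK, placed by the series title downstream of oncostatin M receptor signalling, does for keratinocyte proliferation and differentiation. Between 12087 and 12311 genes per library reached 1 FPKM. Log2 differences below are knockdown minus control on the log2(FPKM + 0.5) scale. Set A (control replicate 1, knockdown replicates 1 and 3) and set B (control replicate 2, knockdown replicate 2) are the libraries that share value steps, and within-set medians are given for lists and within-set differences for some genes. Of 68 tested genes chosen by rule, 63 had the same sign in both sets, and the other 5 were OSMR, IL6ST, PCNA, S100A10 and KRT5. In 57 of the 68 the groups did not overlap, which by itself fixes the same sign in both sets. Over all tested genes 31.98% did not overlap, where chance gives 20%. Apart from AHNAK and the fixed set, the 68 were taken for small p in these same libraries. That choice favours such agreement, so these counts are no independent support.

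AHNAK transcripts were lower in all 3 knockdown libraries than in both controls. AHNAK (ENSG00000124942.13, chromosome 11, 62433542 to 62556235, minus strand, GRCh38) stood at 204.8 and 242.0 FPKM in the controls and at 113.9, 69.6 and 115.3 FPKM in knockdown replicates 1, 2 and 3. The means were 223.4 ± 26.3 FPKM (SD, n = 2) and 99.6 ± 26.0 FPKM (SD, n = 3), a ratio of 0.446. The log2 difference was -1.19 (SE 0.24, 95% confidence interval -1.77 to -0.61), with -0.83 in set A and -1.79 in set B. It did not pass over all genes (limma, Benjamini-Hochberg adjusted p = 0.372), and passed with limma array weights (-1.55, adjusted p = 0.0340). Those weights were 3.98 for knockdown replicate 2, the library of lowest AHNAK, and 0.530 and 0.257 for knockdown replicates 1 and 3. With array weights, the split of knockdown replicates 1 and 2 against the rest also called 2751 genes, so this pass carries little weight. AHNAK2, the closest relative of AHNAK, was also lower without passing, with a log2 difference of -0.78 (set A -0.22, set B -1.60).

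No single gene passed the threshold between knockdown and control. Among genes with a mean of at least 5 FPKM, those of smallest p that were higher in every knockdown library were NTN4, a secreted netrin of basement membranes, FGD3, G3BP2, a stress granule protein, ECI1, a mitochondrial enzyme of fatty acid oxidation, and OGFR, the opioid growth factor receptor. NTN4 averaged 12.05 ± 0.57 FPKM (SD, n = 2) in controls and 23.2 ± 2.36 FPKM (SD, n = 3) in knockdown, a log2 difference of 0.91 (SE 0.14), and the other 4 differed by 0.77 (ECI1) to 1.17 (OGFR). Lower in every knockdown library, and also of small p, were PLAUR, the urokinase receptor, MFSD2A, a lipid transporter, SLC12A4 and UNC13D. PLAUR averaged 23.3 ± 2.43 FPKM (SD, n = 2) in controls and 12.5 ± 0.78 FPKM (SD, n = 3) in knockdown, a log2 difference of -0.87 (SE 0.13), and the other 3 differed by -1.14 (MFSD2A) to -0.72 (SLC12A4). Each of these 9 genes had a limma adjusted p of 0.372. They were chosen as having no overlap between groups, so their signs had to be the same in both sets. Limma called 0 of 12196 genes (smallest adjusted p = 0.0570), while 1427 genes had an unadjusted p under 0.05, 759 higher and 668 lower, where 610 are expected with no effect and independent libraries. That count was 828 with a term for the set of libraries and 564 without control replicate 2, and 2 other splits of the libraries into 2 and 3 gave 1575 and 2287. When each library was rescaled to the same sum, 507 were higher and 809 lower. With limma array weights, which weighted knockdown replicate 2 at 3.98 and knockdown replicate 3 at 0.257, 1428 genes passed, and 9 passed without control replicate 1.

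**Figure D1:**
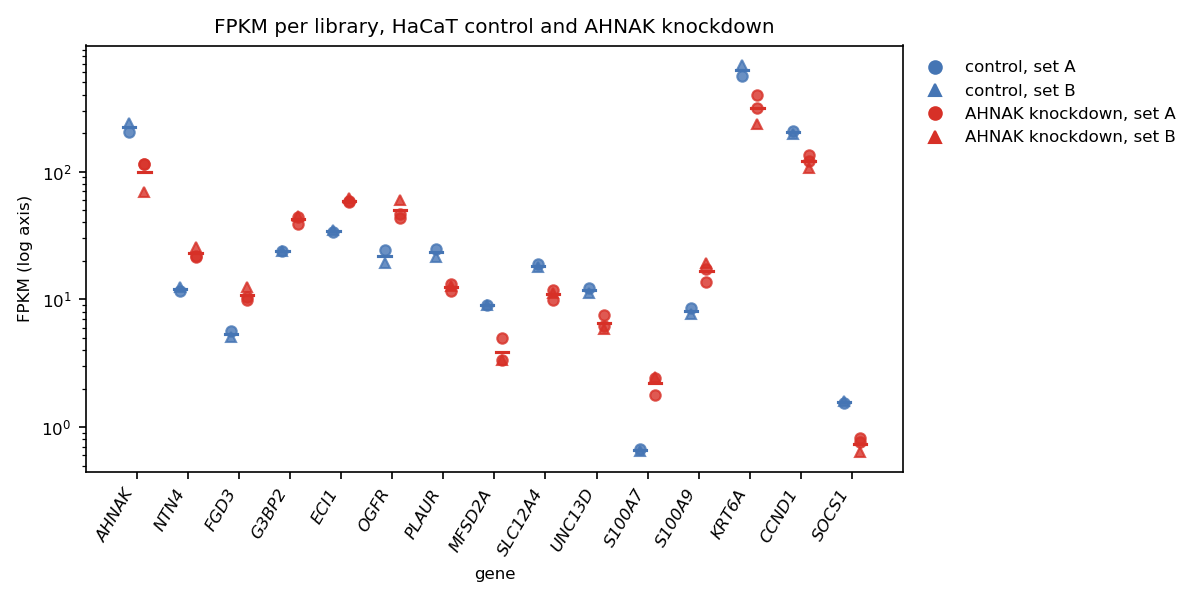
FPKM per library (log axis) of AHNAK, of 9 genes of small p and of 5 keratinocyte and cytokine signalling genes, with circles for set A, triangles for set B and a bar at each group's mean. AHNAK lies between 69.6 and 115.3 FPKM in the 3 knockdown libraries and at 204.8 and 242.0 FPKM in the controls; none of these genes passed the test over all genes.

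Genes of activated, wound-type keratinocytes moved in both directions. S100A7 and S100A9, inflammatory calcium-binding proteins of the epidermis, were higher in knockdown by 1.22 and 0.99 on the log2 scale, S100A7 at a low level of 0.66 ± 0.02 FPKM (SD, n = 2) against 2.23 ± 0.39 FPKM (SD, n = 3). PLAUR was lower, as was KRT6A, a keratin induced by wounding, at 624.3 ± 86.0 FPKM (SD, n = 2) against 315.2 ± 81.6 FPKM (SD, n = 3). Of the 18 tested members, 3 were higher and 5 lower with an adjusted p under the threshold when adjusted over the list alone, and 0 passed over all genes. KRT6A has near-identical copies, and its reads may be divided among them. The list as a whole did not pass in camera (adjusted p = 0.453; median -0.23, set A -0.14, set B 0.02), and passed as lower with genes of mean FPKM of at least 5 only (adjusted p = 0.00728).

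The basal keratinocyte list was lower in knockdown, with 19 of 23 members lower and a median log2 difference of -0.21. LAMA3, a chain of the basement membrane laminin, had a log2 difference of -0.74, and DST, which anchors keratins to hemidesmosomes, -0.39. KRT15, another basal keratin, went the other way, at 0.53. Camera with the preset correlation gave an adjusted p of 0.00632, and the adjusted p was 0.657 with an estimated correlation. The median was -0.11 in set A and -0.29 in set B. Adjusted over the list alone, 0 members passed, and without knockdown replicate 3 the list's adjusted p was 0.0553 (median -0.22). After correction for GC content and transcript length it was 0.0687 (median -0.15).

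Differentiation genes did not move together. In the cornified envelope list, IVL (involucrin, a precursor of the envelope) was at 28.1 ± 4.75 FPKM (SD, n = 2) in controls and 52.1 ± 14.9 FPKM (SD, n = 3) in knockdown. Its log2 difference was 0.46 in set A and 1.47 in set B. SPRR1B was also higher, by 0.79 (set A 0.29, set B 1.57). FLG (filaggrin) and TGM1, the transglutaminase that crosslinks the envelope, were lower, with log2 differences of -0.93 (set A -1.33, set B -0.39) and -0.50 (set A -0.26, set B -0.85). Of its 23 members 17 were lower and 6 higher, and the list did not pass (camera adjusted p = 0.307). Its median was -0.12 and its mean 0.01, so these differ in sign. In the early differentiation list, 19 of 28 members were lower (median -0.09, camera adjusted p = 0.242), with GRHL3 at -0.48, PKP1 at -0.64, KRT4 at 0.54 and KRT13 at 0.36. KRT1 and KRT10, the keratins of the spinous layer, differed by 0.18 and 0.25. The median of the early list was 0.18 in set A and -0.22 in set B, and that of the cornified list was 0.01 and -0.13. Neither list had a member past the threshold, over all genes or adjusted over the list alone. Without control replicate 1 the early list passed as lower (camera adjusted p = 0.003055, median -0.25).

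Cell cycle genes did not pass as lists in the main fit. MKI67, a marker of proliferating cells, was at 65.5 ± 3.61 FPKM (SD, n = 2) in controls and 46.7 ± 10.3 FPKM (SD, n = 3) in knockdown, a log2 difference of -0.51 (set A -0.53, set B -0.52). Among the other members of smallest p, CCNE1 (-0.59), CCNE2 (-0.36), E2F2 (-0.65), CLSPN (-0.51), ANLN (-0.35) and CDC20 (-0.35) were lower and BIRC5 (0.39) was higher. PCNA differed by 0.24 (set A 0.52, set B -0.17). The G1/S list had 31 of 47 members lower (median -0.07, camera adjusted p = 0.103; set A -0.09, set B -0.13). The G2/M list had 31 of 51 lower (median -0.03, camera adjusted p = 0.242). In set A 36 of the 51 G2/M members were higher, and in set B 49 were lower, with medians of 0.07 and -0.25. Without knockdown replicate 3 the G2/M list passed as lower (camera adjusted p = 0.00104, median -0.14), and the G1/S list passed as lower without control replicate 2 (0.0408) or knockdown replicate 1 (0.0185). With limma array weights both passed as lower (G1/S 0.01123, median -0.14; G2/M 0.0002003, median -0.17). These list calls all used the preset correlation. In the main fit an estimated correlation gave camera adjusted p of 0.774 for G2/M and 0.665 for G1/S. Among the libraries, knockdown replicate 3 lay highest for G2/M (median deviation 0.22) and knockdown replicate 2 lowest (-0.19). Array weights weighted these 2 libraries at 0.257 and 3.98. Adjusted over the list alone, 0 members of either list passed.

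Within the oncostatin M receptor and STAT3 list, CCND1 (cyclin D1) and SOCS1, a feedback inhibitor of cytokine signalling, were lower in every knockdown library. CCND1 was at 204.1 ± 7.49 FPKM (SD, n = 2) against 120.7 ± 13.5 FPKM (SD, n = 3), a log2 difference of -0.76 (set A -0.72, set B -0.89), and SOCS1 at 1.58 ± 0.03 against 0.74 ± 0.10 FPKM. These 2 passed when adjusted over the list alone, and 0 of 34 members passed over all genes. ICAM1 differed by -0.69 and CEBPD by 0.47. The receptor chains OSMR and IL6ST were at -0.24 (set A -0.53, set B 0.16) and -0.41 (set A -0.78, set B 0.10), STAT3 at 0.05 and SOCS3 at -0.41. IL31RA was near 0 in every library, at 0.034 to 0.162 FPKM, and was not tested. The list had 22 of 34 members lower (median -0.20, set A -0.17, set B -0.01), and camera gave an adjusted p of 0.0545. Without control replicate 2 or knockdown replicate 2 it was 0.00740 and 0.0132, and with quantile normalization 0.04909.

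The list of genes tied to localised cutaneous amyloidosis did not pass (median 0.02, camera adjusted p = 0.884; set A 0.04, set B 0.15), with 8 of 15 members higher and 7 lower. GPNMB was higher by 2.05 on the log2 scale, resting on control replicate 2 at 7.13 FPKM, since control replicate 1 was at 42.8 FPKM and the knockdown libraries at 54.6 to 122.8 FPKM. Without control replicate 1 its log2 difference was 3.30 and passed. KRT14 differed by -0.70 (set A -0.26, set B -1.38), KRT5 by -0.23 (set A 0.03, set B -0.56), GSN by -0.63 and CLU by 0.31. Among AHNAK's partners and relatives 13 of 20 members were lower (median -0.10, camera adjusted p = 0.242; set A -0.17, set B -0.12). RAC1 differed by 0.56, MSN by -0.47 and LIG4 by -0.39. S100A10 and ANXA2, which bind AHNAK, differed by 0.17 (set A 0.47, set B -0.25) and -0.10. In both lists 0 members passed when adjusted over the list alone.

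Interferon-stimulated genes were higher as a group, with 32 of 37 members higher and a median log2 difference of 0.43. SAMD9L, RSAD2 and IFI6, antiviral genes, had log2 differences of 0.81, 0.89 and 0.79. Within set A these were 0.38, 0.40 and 0.41, and in set B, with 1 library per group, 1.44, 1.63 and 1.41. The list median was 0.22 in set A and 0.76 in set B. Knockdown replicate 2 lay highest, at a median deviation of 0.45 from the mean of the 5 libraries. In set A, the values of 9 of the 37 members scaled between libraries in proportion to the worth of 1 read (within 0.1 on the log2 scale). That scaling by itself gives a difference of 0.39 there. SAMD9L, RSAD2 and IFI6 are among these 9 members, and their set A differences lay near that value. Camera gave an adjusted p of 6.14e-07, and the adjusted p was 0.657 with an estimated correlation. Adjusted over the list alone, 0 members passed.

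Cytosolic ribosomal proteins and nuclear-encoded subunits of oxidative phosphorylation were higher as groups in the pooled comparison and not in set B. Of 74 ribosomal proteins 71 were higher (median 0.22; set A 0.40, set B -0.0035), among them RPL11 (0.58) and RPL28 (0.28), which have many processed pseudogenes that can share their reads. Of 42 oxidative phosphorylation genes 37 were higher (median 0.15; set A 0.28, set B -0.04), among them NDUFA4 (0.52) and UQCRC2 (0.26). Knockdown replicate 3 lay highest in both, at median deviations of 0.41 and 0.31. Camera gave adjusted p of 2.28e-06 and 0.00632, and both adjusted p were 0.657 with an estimated correlation. Without knockdown replicate 3 the adjusted p were 0.119 and 0.277, and without control replicate 1 they were 0.3004 and 0.404. Over all genes, deviations of knockdown replicate 3 were correlated with GC content and transcript length at Spearman's rho of -0.549 and -0.212 and those of knockdown replicate 1 with GC content at 0.605, and after correction for both the oxidative phosphorylation median was 0.09 (adjusted p = 0.0501). Adjusted over each list alone, 0 members passed.

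The NF-kappaB, cytokine and chemokine list was lower in the pooled comparison and went in opposite directions in the sets. Of 26 members 21 were lower (median -0.23), with medians of -0.58 in set A and 0.33 in set B. IL1B was at 103.3 and 63.4 FPKM in control replicates 1 and 2 and at 36.5, 50.3 and 32.3 FPKM in knockdown replicates 1, 2 and 3, and TRAF1 and CSF2 differed by -1.43 (set A -2.30, set B -0.17) and -0.77 (set A -1.25, set B -0.13). Camera gave an adjusted p of 0.0132, and the adjusted p was 0.657 with an estimated correlation. Without control replicate 1 the adjusted p was 0.584, and without knockdown replicates 1 and 3 in turn it was 0.236 and 0.110. After correction for GC content and transcript length it was 0.0501 (median -0.29). Adjusted over the list alone, 0 members passed.

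**Figure D2:**
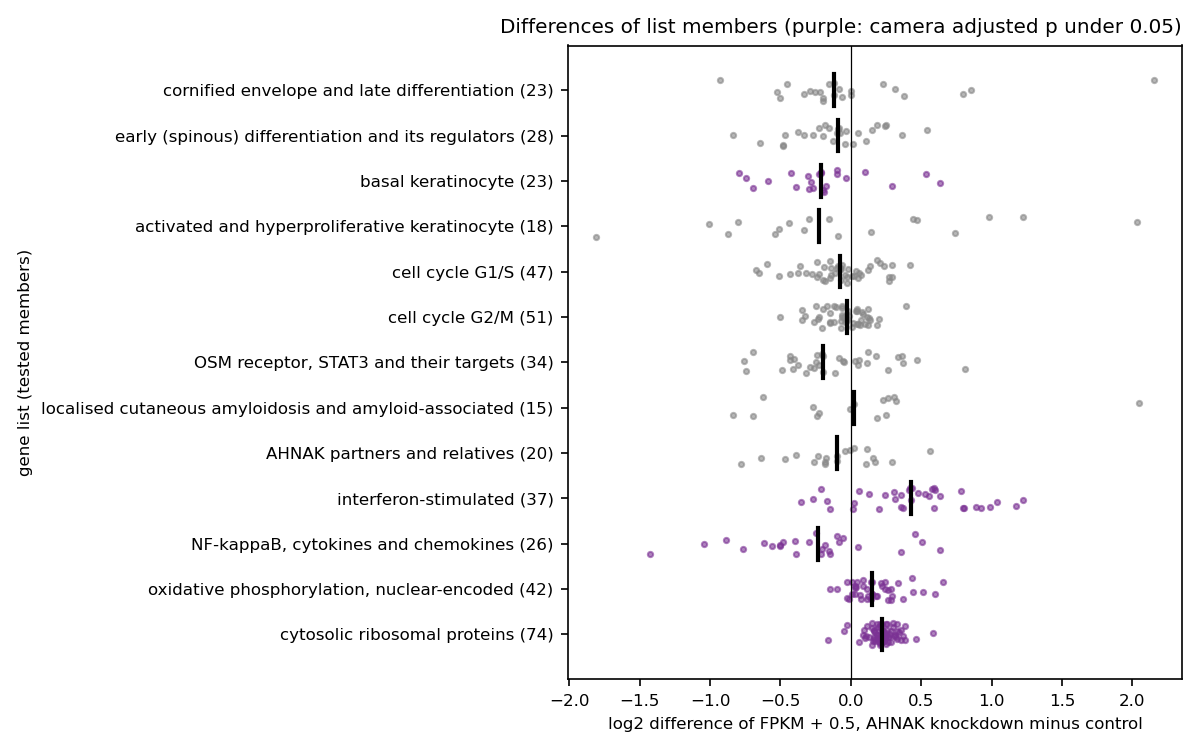
Log2 difference (knockdown minus control, FPKM + 0.5) of each tested member of the 9 main lists and of the 4 other lists past the threshold, with the number of tested members in brackets and a black bar at the median. Purple marks the 5 lists with a camera adjusted p under 0.05 at the preset correlation; the medians run from -0.23 in the NF-kappaB list to 0.43 in the interferon list.

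**Figure D3:**
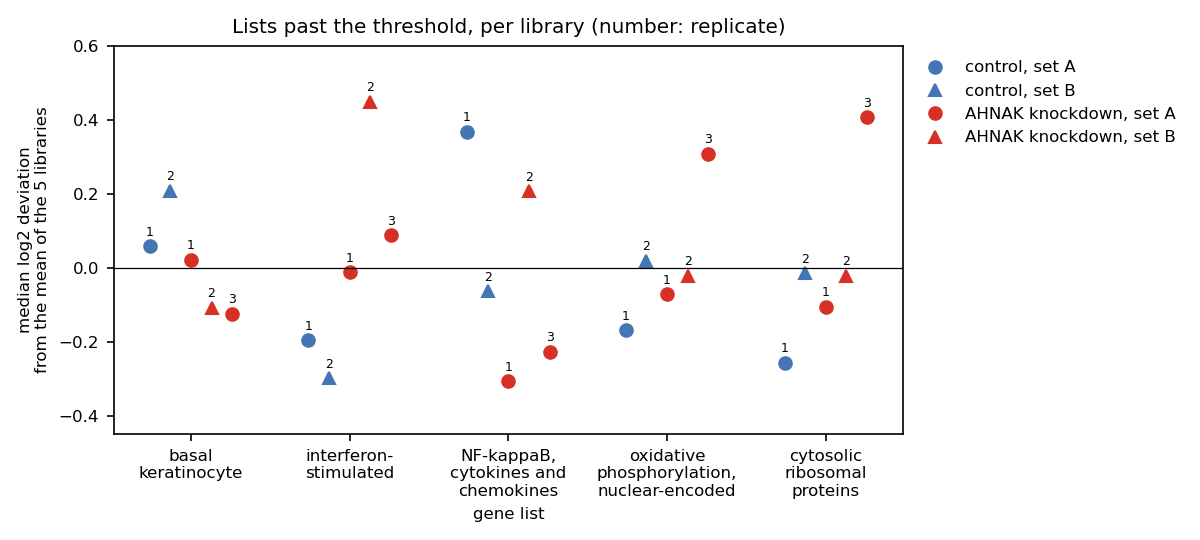
Median log2 deviation from the mean of the 5 libraries for the 5 lists past the threshold, 1 point per library, with circles for set A, triangles for set B and the replicate number above each point. Knockdown replicate 2 is highest for the interferon list (0.45) and knockdown replicate 3 for the ribosomal list (0.41).

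In all, 5 of 29 lists passed in camera with the preset correlation, 3 higher and 2 lower, and 0 passed with an estimated correlation or with fry (smallest adjusted p = 0.657 and 0.464).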

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

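AHNAK stayed lower in every fit run, and passed the threshold only with array weights (-1.55). Over all alternatives, named genes other than AHNAK kept their sign in 1254 of 1264 fits, and 40 of 67 passed in at least 1 fit, GPNMB without control replicate 1 and the rest with array weights. The set term, the GC content and length corrections and camera with a variance trend were chosen after the data had been seen, and the cause of the changes below was not tested unless stated. The fits without a trend and with robust empirical Bayes were run for genes only and gave no list values. Values below for lists are camera adjusted p.

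One gene or more passed with a pseudocount of 1 (1 gene), without a trend (1), with robust empirical Bayes (1), with adjusted p under 0.1 (1) and with array weights (1428). Genes with an unadjusted p under 0.05 numbered 862 with mean FPKM at least 5, where 8677 genes were tested, 4285 with array weights, 828 with the set term and 2143 with the GC content and length correction. Lists past the threshold numbered 3 without a filter, 9 at mean FPKM of at least 5, 8 with quantile normalization, 2 with the GC content and length correction, and 0 with an estimated correlation (0.6573 for each of the 5 lists) and with fry (0.4958 for the basal and interferon lists, 0.5705 for the other 3). Without a filter the basal and NF-kappaB lists were both at 0.05596. The NF-kappaB list was at 0.05616 after rescaling to an equal sum and 0.6344 with array weights, and oxidative phosphorylation at 0.2672 with array weights. With the GC content and length correction the basal list was at 0.06871 and the NF-kappaB and oxidative phosphorylation lists at 0.0501, with medians of -0.15, -0.29 and 0.09.

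Correlations of deviations between samples of the same replicate number were -0.064 for number 1 and -0.578 for number 2. They cannot decide whether the numbers pair the samples. Deviations of 2 controls mirror each other, and control replicate 2 and knockdown replicate 2 form set B. If the sets were brought to equal means per gene before deposit, a negative correlation there could be built in. A replicate block, in which knockdown replicate 3 has a number of its own and drops out, gave 0 genes past the threshold and AHNAK at -1.32. List values under the block were 0.06827 (basal), 0.07715 (NF-kappaB), 0.2822 (oxidative phosphorylation) and 0.1299 (ribosomal proteins), and the interferon list kept its call. With the GC content and length correction and the block, 1 gene passed, and the basal, oxidative phosphorylation and ribosomal lists were at 0.06601, 0.5506 and 0.3803.

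Leaving out each library in turn gave 0 to 9 genes past the threshold (9 without control replicate 1, which leaves 1 control assumed to vary like the knockdown libraries), 564 to 2092 with an unadjusted p under 0.05, 4 to 12 lists, and AHNAK at -1.32 to -0.96. Adjusted p ran from 0.003055 to 0.05526 for the basal list, 3.167e-08 to 0.5838 for NF-kappaB, 1.791e-05 to 0.4038 for oxidative phosphorylation, 2.567e-12 to 0.3004 for ribosomal proteins and 7.251e-09 to 5.452e-06 for the interferon list.

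Signs of several results turned; for lists, this is the direction of the camera test, which the median did not always share. STAT3 was at -0.0008 after rescaling to an equal sum. S100A10 was at -0.0271 with array weights, -0.0785 with the block and -0.1212 with the block and correction, and PCNA at -0.0042 and -0.0183 in the last 2. The cornified list turned at mean FPKM of at least 5 (0.6892; median still lower, -0.0316), and the amyloidosis list with quantile normalization (0.9323), the block (0.9807; median still higher, 0.0053) and the block and correction (0.7573). Leaving out each library gave -0.1168 to 0.4834 for KRT1, -0.0042 to 0.3956 for PCNA and -0.0785 to 0.3528 for S100A10. It gave adjusted p of 0.003055 (lower, without control replicate 1) to 0.707 (without control replicate 2, camera direction higher, median still lower at -0.0298) for early differentiation, 0.001039 to 0.9653 for G2/M, which was higher without knockdown replicate 2 (0.5098), and 0.707 to 0.9666 for amyloidosis. G2/M passed as lower with the block (0.00181), with the block and correction (0.009684) and with array weights (0.0002003), as did G1/S with array weights (0.01123).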

Other observations

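All tests of explanations in this part were chosen after the results were seen. Several other lists lay close to the threshold in camera. NRF2 targets, the antioxidant programme, were higher (median 0.16; set A 0.28, set B 0.01; adjusted p = 0.0545), with 15 of 24 members higher. Actin cytoskeleton genes (27 of 36 lower, median -0.11; set A -0.10, set B -0.15) and YAP and TEAD targets (15 of 23 lower, median -0.22; set A -0.34, set B -0.0029) were lower, each with an adjusted p of 0.0545. With an estimated correlation the adjusted p was 0.657 for each of these 3. Cholesterol synthesis genes were higher in set B (median 0.40, 26 of 31) and not in set A (-0.06), with a pooled median of 0.15 and an adjusted p of 0.0734. When adjusted over that list alone, 2 genes passed, 1 higher and 1 lower: INSIG1, a sterol sensor partner, at 0.61, and FADS1, a fatty acid desaturase, at -0.74. Both were named after their values were seen.

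The remaining lists had camera adjusted p of 0.108 (immediate early and AP-1, median -0.26), 0.174 (epithelial to mesenchymal transition and matrix, -0.13), 0.242 (p53 targets, -0.05), 0.307 (heat shock and chaperones, 0.06), 0.356 (hypoxia and glycolysis, median 0.0005 and mean -0.04), 0.453 to 0.454 (activated keratinocyte; TGF-beta targets, -0.04; junctions, -0.05; histones, 0.05), 0.477 (ribosome biogenesis, -0.04; RNA interference machinery, -0.05) and 0.721 (unfolded protein and integrated stress response, -0.01). Keratins and other markers of simple epithelium (5 tested, median -0.10) had an adjusted p of 0.307, at summed levels of 2771 to 3295 FPKM, with KRT19 the highest. Markers of 4 other cell types stayed low in every library: summed FPKM ran from 5.86 to 12.2 for fibroblast, 2.78 to 3.63 for melanocyte, 17.0 to 35.3 for immune and 3.29 to 5.01 for endothelial markers, the immune sum being mostly CD68. The fibroblast and immune sums ordered the 5 libraries as the interferon-stimulated list did, lowest in control replicate 2 and highest in knockdown replicate 2, and the cause was not tested.

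The gene of smallest p was MIR4260, named after its values were seen. Its 67 bp (chromosome 1, 209623444 to 209623510, minus strand, GRCh38) overlap an exon of LAMB3, a laminin chain. MIR4260 was at 4.07 and 3.28 FPKM in the controls and at 0.363, 0.279 and 0.416 FPKM in knockdown replicates 1, 2 and 3, a log2 difference of -2.29 (set A -2.36, set B -2.28) with a limma adjusted p of 0.0570. LAMB3 itself differed by -0.31 (set A -0.35, set B -0.23). Reads of a gene this short inside an exon cannot be assigned to it with certainty.

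The 5 libraries fall into 2 sets that no label describes, recognised by shared steps of their low values. On the scale of reads, the mean of each gene was nearly the same in the 2 sets: the median absolute log2 ratio of set means was 0.0431, against 0.1093 or more for the other 9 splits of the libraries into 2 and 3. With the ratios centred, which removes the unsettled scale between the sets, these were 0.0409 and 0.1066 or more. A candidate explanation is that values of the 2 sets were brought to equal means per gene before they were deposited. If so, the spread between libraries may be understated, and p-values could be too small. No biological explanation was tested for this pattern.

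The higher interferon-stimulated genes have different weight in the 2 sets. Correction for GC content and transcript length took the list's median from 0.43 to 0.39, so the trends as fitted removed little of it. The camera adjusted p was then 8.55e-05 at the preset correlation. That adjusted p cannot decide on the cause, since with an estimated correlation the list was at 0.657 before any correction. In set A, the members varied less between libraries on the read scale (median log2 range 0.257) than all 10000 random lists of the same size and expression (lowest 0.337; share 0.0001, the smallest these draws can give), and 9 of 37 scaled only with the worth of 1 read, as did 211 of 12159 other genes (Fisher's exact test, adjusted p = 4.00e-07 over 29 lists). Neither test can decide the cause. On the read scale the median set A difference of all tested genes was -0.401, so a list higher there varies less by that alone. Both tests also treat the members as independent, while camera estimated a correlation of 0.45 between them. For these 9 members the difference in set A may be carried over from set B by the adjustment and then scaled by reads per library. For the other 28 (set A median 0.1852, set B 0.6604) this stays open as well. On the read scale, where such a carry-over gives 0, their median in set A was -0.1932 (quartiles -0.2929 and -0.1478), with 26 of the 28 lower. They are the members left after those near 0 were set apart, so no test was made. Also open is set B, where the median was 0.76 from 1 control and 1 knockdown library: AHNAK knockdown, a response to the introduced RNA and a difference between these libraries cannot be told apart with 1 library per group.

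The higher ribosomal proteins were tested against library effects. Correction for GC content and transcript length took the median from 0.22 to 0.18, with a camera adjusted p of 6.45e-04 at the preset correlation. That adjusted p cannot decide on these trends, since camera estimated a correlation of 0.87 between the members. With an estimated correlation the list was at 0.657 before any correction. With the correction and the replicate block, which drops knockdown replicate 3, the median was 0.05 (camera adjusted p = 0.3803). The list follows knockdown replicate 3, without which the adjusted p was 0.119 and the median 0.07. Control replicate 1 also holds it up, with a median of 0.11 and an adjusted p of 0.3004 without it. A property of single libraries is consistent with these values, and AHNAK knockdown stays open as untested. Median deviations from the mean of the 5 libraries were -0.26 and -0.02 in control replicates 1 and 2 and -0.11, -0.02 and 0.41 in knockdown replicates 1, 2 and 3.

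With 10 splits of the 5 libraries into 2 and 3, the share of splits with as many genes cannot fall under 0.05. The real split gave 1427 genes with an unadjusted p under 0.05 and the highest of the others 2287 (knockdown replicates 2 and 3 against the rest), with 3 of 10 splits at or above the real one. With array weights the real split called 1428 genes and the split of knockdown replicates 1 and 2 against the rest 2751, while the other 8 splits called 0 to 3. What sets these 2 splits apart was not tested.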
